A study of Drosophila melanogaster with 4 samples.

How the data were processed

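The series is a ChIP-seq experiment on the acetylated lysine 9 of histone H3 (H3K9ac), a histone mark found at active promoters, in third-instar larvae of the wild-type Drosophila melanogaster strain Oregon-R. The labels name 4 samples, 2 immunoprecipitated (ChIP) libraries and 2 input libraries of chromatin that was not enriched. Larval tissue was homogenised, fixed with formaldehyde and sonicated, and the ChIP was collected on beads after incubation with the antibody, per the labels' protocols. Whole larvae hold many tissues, so each value is an average over cell types. The labels do not say whether the replicates came from separate collections, so the spread between them may be partly technical.

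In all, 3 lists were used, 1 for each ChIP replicate and 1 for the replicate set. Each holds regions of significant enrichment, called clusters here, with a start, an end and a value per cluster. Reads were mapped with Bowtie 0.12.7, per the submitters' processing notes. Positions refer to FlyBase release 5, per the file headers. The peak caller, its threshold, the input set against each ChIP library and the way the replicates were combined are not given in the sources used here. The deposited value per cluster, called the score, behaves as a log2 value. The scale was inferred from ties: among the 40 most frequent scores of each list, 700, 768 and 763 of 780 differences were log2 of a ratio of whole numbers with denominators up to 5000 (relative tolerance 1e-11) in replicate 1, replicate 2 and the replicate set, against at most 1 under natural log or log10. A score of 1 would then be a ratio of 2, but the quantity the authors put in the denominator of this log2 ratio is not stated. Scores are the authors' own values, and which part of a cluster each one describes is also unstated.

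The files give no read counts, so the depth of the 4 libraries is unknown, and no counting interval is given. No processed file of the input libraries was used here. The background therefore enters only through the authors' calling of enrichment. The reference table at hand follows release 6 of the genome, and its positions were not converted to release 5 here. For that reason clusters were not assigned to genes, and the planned comparisons of promoters, of positions relative to transcript starts and of gene lists fixed beforehand were not run. Clusters are named by position only.

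Cluster ends were read as the GFF3 format defines them, 1-based and inclusive. One cluster of the replicate set starts at position 0, so the convention is uncertain by 1 bp. No other per-sample columns were present. Clusters were compared by overlap of at least 1 bp. Overlap was tested one-sided against 1000 circular shifts of a list within each sequence, for which the smallest possible p is 0.001. Scores of the replicates were compared over clusters that overlapped exactly 1 cluster of the other list. The shares of sequence covered in both replicates, and the mean scores of paired clusters, were computed in 100 kb bins. They were compared between X, chromosome 4 or the 6 heterochromatic (Het) sequences and the 4 autosome arms by a two-sided permutation test of the bins with 100000 resamples, with Benjamini-Hochberg adjustment over the 3 comparisons and a threshold of 0.05. The smallest p it can give is 1e-05. Intervals are 95% percentile intervals from 2000 bootstrap draws of bins. Bins are not biological replicates and neighbouring bins are not independent, so these p-values describe the 2 ChIP libraries and are likely too small.

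The comparison of covered shares and the overlap measures were chosen before the data were examined, as was the rule for named regions: the 5 regions covered in both replicates with the highest mean score, the 5 longest such regions, the 3 highest-scoring clusters of each replicate with no partner, and the 5 longest stretches without a cluster on the 5 large arms. The score comparisons between sequences and the comparisons between parts of the arms were added after the data were seen, once the log2 scale had been inferred. The plan had been to use scores only to rank clusters. Score differences between the replicates are described as they stand and were tested only relative to those in the arm middles, with Benjamini-Hochberg adjustment over 8 comparisons. Alternatives were the 50% of each list with the highest scores, a minimum of 50% of a cluster's length for overlap, each replicate alone, the replicate-set list and 50 kb bins, and, added later, arms without their 2 Mb ends and 1 Mb bins. No cluster had the same start and end in both replicates.

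The tests were tested on simulated data. With 190 X bins and 852 autosome bins drawn without a difference, 5.6% of 1000 simulations passed an unadjusted p of 0.05, and with a difference of 0.14 all 1000 passed (100%). These bins were drawn as independent normal values, so the check does not cover the dependence between neighbouring bins. Circular shifts called 1.5% of 200 pairs of independent lists and 100% of 200 pairs that shared 30% of their clusters. Those lists held clusters of equal length placed at random on 2L alone, unlike the real lists. Both checks used fewer resamples or shifts than the tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.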

Results

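H3K9ac was mapped by ChIP-seq in whole third-instar larvae, with 2 ChIP libraries and 2 input libraries. H3K9ac clusters covered 20.9 Mb in replicate 1 and 22.3 Mb in replicate 2, which is 17.3% and 18.5% of the 5 large chromosome arms (17.9% ± 0.875, SD, n = 2). Replicate 1 held 6545 clusters and replicate 2 held 7629 (7087 ± 767, SD, n = 2), of which 98.3% and 98.7% lay on the large arms. The median cluster was 2548 bp long in replicate 1 and 2321 bp in replicate 2, and 89 and 84 clusters were longer than 10 kb. The median score, taken as a log2 value, was 0.77 in replicate 1 and 0.66 in replicate 2, which as ratios would be 1.71 and 1.58. Longer clusters scored higher in each replicate. Clusters of 1301 to 2000 bp had a median score of 0.46 in replicate 1 and 0.49 in replicate 2, and clusters above 10 kb had medians of 1.21 and 1.28. The depth of the libraries is unknown.

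The 2 ChIP replicates show how far separate libraries marked the same sequence. Strong H3K9ac clusters were found in both larval libraries, and clusters found in a single library were short and weak. Of the 1546 replicate 2 clusters with scores from 1 to 1.5, 99.9% had a partner in replicate 1, and all 580 above 1.5 did (100%). In replicate 1, 99.9% of the 1696 clusters with scores from 1 to 1.5 had a partner in replicate 2. At scores from 0.5 to 1, the largest class in each replicate, the shares were 89.022% of 2833 clusters in replicate 1 and 73.997% of 3988 in replicate 2. At scores up to 0.5 they were 64.6% of 1298 clusters in replicate 1 and 57.8% of 1515 in replicate 2. The lack of partners in replicate 2 was thus not limited to the lowest scores. Over the whole lists, 88.2% of replicate 1 clusters and 78.0% of replicate 2 clusters overlapped the other list, against 32.7% and 29.1% on average after circular shifts. The lists shared 17.7 Mb, a Jaccard index of 0.696 and 4.57 times the mean of 3.88 Mb over 1000 shifts (one-sided permutation p = 0.001, the smallest these shifts can give). The 773 clusters of replicate 1 without a partner had a median score of 0.48 and a median length of 1622 bp, and the 1677 of replicate 2 had medians of 0.53 and 1582 bp.

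Scores ranked clusters alike in the 2 libraries. Across 4896 clusters that overlapped 1 cluster each way, Pearson's r was 0.921 and Spearman's rho 0.905. This is a correlation across clusters, which are not independent replicates. The paired score was higher in replicate 1 by 0.05 on average, with an SD of 0.17 over pairs, and 59.3% of pairs were higher in replicate 1.

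The highest-scoring regions marked in both larval libraries lay on U, 2L, 3R and 2R. The highest was a 2123 bp region of the unplaced sequence U, from position 5540985 to 5543107, with a mean score of 2.71 ± 0.74 (SD, n = 2), or 3.23 in replicate 1 and 2.19 in replicate 2. The next were on 2L from 19007484 to 19010180 (2.57 ± 0.07), on 3R from 26032609 to 26035589 (2.36 ± 0.18), on 2R from 7776655 to 7783082 (2.36 ± 0.24) and on 2L from 558715 to 561329 (2.33 ± 0.15), all means ± SD of the 2 replicates. The longest stretch marked in both was 18121 bp on 2R, from 8054427 to 8072547, with a mean score of 1.71 ± 0.09 (SD, n = 2). It was followed by 17764 bp on X from 9041709 to 9059472, 16525 bp on X from 652855 to 669379, 16318 bp on 2L from 11986601 to 12002918 and 15040 bp on 3L from 539066 to 554105. In all, 6230 regions were covered in both replicates. Of these, 46 exceeded 10 kb, 13 on 3R, 12 on 2L, 8 on 2R, 8 on X and 5 on 3L. The replicates differed at a few higher-scoring clusters. The 3 highest-scoring clusters without a partner in replicate 2 were all on U, at 8927136 to 8928794 (score 1.69), 3442598 to 3444969 (1.03) and 1101860 to 1104111 (0.90). The 3 highest without a partner in replicate 1 were all on X, at 8603819 to 8606425 (1.03), 18381458 to 18384207 (0.99) and 14366552 to 14369989 (0.93).

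Long unmarked stretches interrupted the arms. The longest without a cluster in either replicate was 478 kb on 2L, from 15771745 to 16249980, and it also held 0 clusters of the replicate set. The others were 367 kb on X from 20530777 to 20897902, 364 kb on 3L from 13508044 to 13871608, 344 kb on X from 21501956 to 21845743 and 335 kb on 2L from 17040918 to 17375775, which held 4, 2, 1 and 1 clusters of the replicate set. Among the 117 full 1 Mb windows, the median share covered in both replicates was 15.0%. The densest window, on 2R from 3000001 to 4000000, reached 27.3%, and the next, on 3R from 5000001 to 6000000, reached 26.6%. The sparsest was on 3L from 23000001 to 24000000, near the centromere, with 1.62%. How much of these windows and unmarked stretches could be mapped is not known here.

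**Figure D1:**
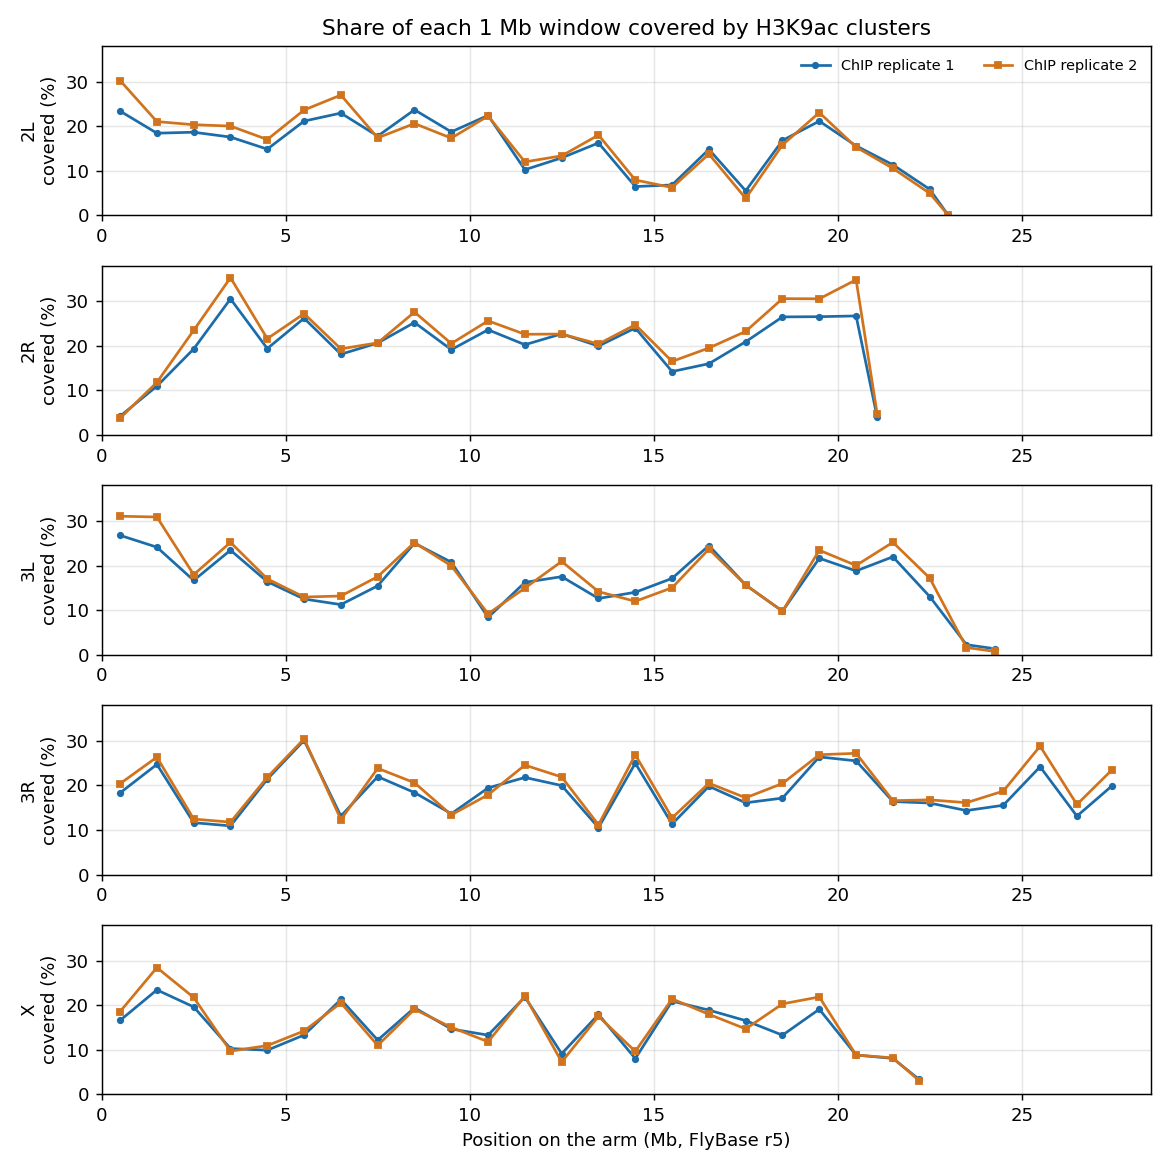
Share of each 1 Mb window (y axis, percent) covered by H3K9ac clusters along the 5 large arms (x axis, Mb, FlyBase release 5) in ChIP replicate 1 (blue) and ChIP replicate 2 (orange), with a shorter last window. The highest point of each replicate is in the window of 2R that starts at 3000001, at 30.5% in replicate 1 and 35.3% in replicate 2, and the lowest is 0% in the short last window of 2L.

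The lists also allow the chromosomes to be compared, namely X, the small chromosome 4 and the heterochromatic sequences with the autosome arms. Coverage was highest on 2R (21.7% ± 1.59, SD, n = 2) and 3R (19.2% ± 1.01), and lower on 3L (17.1% ± 0.792), 2L (16.2% ± 0.563) and X (15.4% ± 0.444). Chromosome 4, which is gene-bearing but rich in heterochromatin, was covered to 10.98% in replicate 1 and 8.35% in replicate 2. The 6 Het sequences, assembled from pericentromeric regions and the Y chromosome, were covered to 1.22% and 0.969%. They still held 43 clusters in replicate 1 and 38 in replicate 2, with 3 and 1 on YHet. In 100 kb bins, the share covered in both replicates differed from that of the 965 autosome bins by -14.2 percentage points on the 93 Het bins (95% interval -15.1 to -13.4, permutation test, adjusted p = 3e-05) and by -7.17 points on the 14 bins of chromosome 4 (-9.26 to -5.18, permutation test, adjusted p = 0.026), and both were lower in each replicate alone. For chromosome 4 the difference was -11.1 points in replicate 2 alone. In the longer replicate-set list the differences were -25.5 points for the Het sequences and -15.8 points for chromosome 4. Values of a single list count all sequence it covers, so they start from a higher base. The autosome bin mean was 15.2% for sequence covered in both replicates. It was 17.8% in replicate 1 alone, 19.2% in replicate 2 alone and 26.7% in the replicate-set list. How much of the Het sequences could be mapped is not known here.

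**Figure D2:**
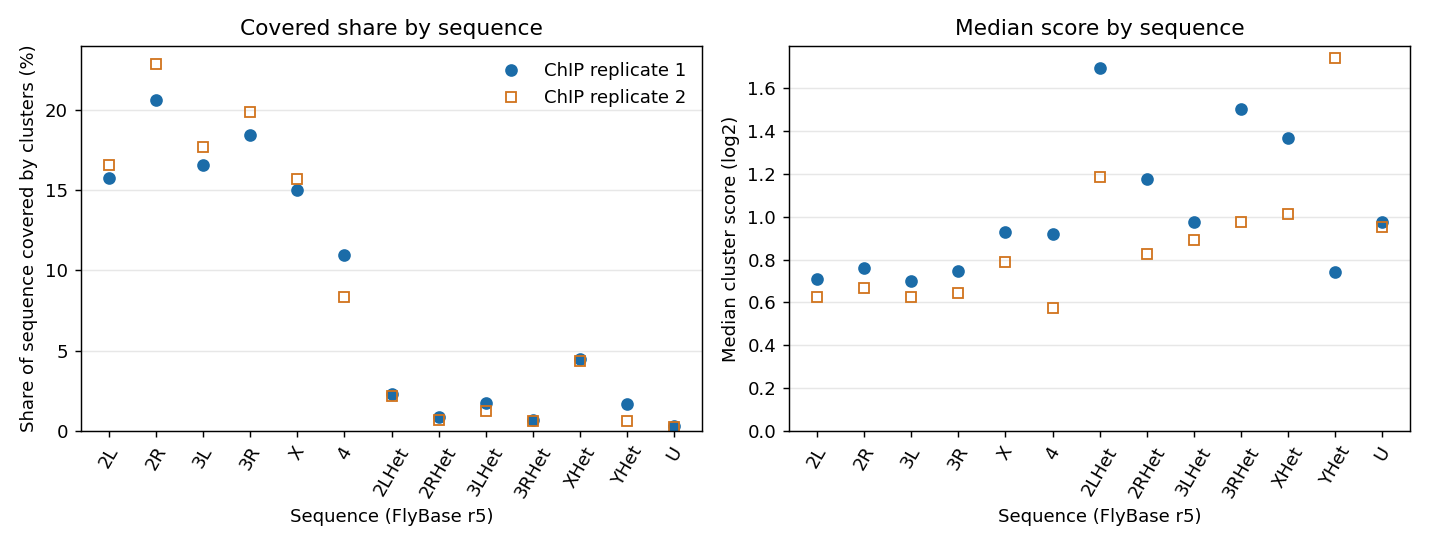
Share of each sequence covered by clusters (left, percent) and median cluster score (right, log2) in ChIP replicate 1 (filled circles) and ChIP replicate 2 (open squares). The 5 large arms lie between 15.0% and 22.9% covered, chromosome 4 at 10.98% and 8.35%, and every Het sequence below 5%, and YHet rests on 3 clusters in replicate 1 and 1 in replicate 2.

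The X chromosome carried fewer clusters than the autosome arms, and those it carried scored higher. The larvae were not separated by sex as far as the labels say. Neither the number of X copies nor the read depth on X was taken into account. There were 46.4 clusters per Mb on X against 55.8 on the autosome arms in replicate 1, and 51.5 against 66.0 in replicate 2. The median score on X was 0.93 against 0.73 in replicate 1 and 0.79 against 0.64 in replicate 2. Clusters scoring up to 1 were sparser on X than on each of the 4 autosome arms in both replicates, at 25.4 per Mb on X against 32.7 to 40.0 on the arms in replicate 1 and 32.1 against 43.2 to 54.8 in replicate 2. Clusters scoring above 1 were within the range of the arms, at 21.0 per Mb on X against 17.1 to 23.1 in replicate 1 and 19.4 against 15.2 to 20.2 in replicate 2. The mean score of paired clusters per 100 kb bin was higher on X by 0.14 (0.09 to 0.18, 190 X bins and 852 autosome bins, permutation test, adjusted p = 3e-05). The share covered in both replicates was lower on X, with a difference of -2.42 percentage points (-3.98 to -0.798, 224 and 965 bins, permutation test, adjusted p = 0.0087). The replicate-set list covered more of X and of the autosome arms, at 21.8% against 26.7% per bin, a difference of -4.89 points. By whole sequence, the share covered in both replicates was 12.7% on X, 13.1% on 2L, 13.8% on 3L, 15.9% on 3R and 18.0% on 2R. The test pooled the 4 autosome arms, which differ among themselves, so it does not set X apart from 2L or 3L. The differences in score and in coverage had the same direction in each replicate alone. There, scores were not limited to paired clusters, nor coverage to sequence covered in both replicates. The difference in coverage was gone among the 50% of clusters with the highest scores, where it was 0.112 points (-1.25 to 1.55). In 1 Mb bins it was of similar size, -2.16 points (-4.32 to -0.0683, 22 X bins), but did not pass the threshold (permutation p = 0.099). The score difference fell to 0.038 (-0.0013 to 0.08, permutation test, adjusted p = 0.07) in the same 50% of clusters, and a selection on the score itself narrows it by construction. This selection also keeps a larger share of the X clusters than of the autosome clusters, since those on X scored higher. The coverage deficit on X was thus seen only with the lower-scoring clusters included.

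**Figure D3:**
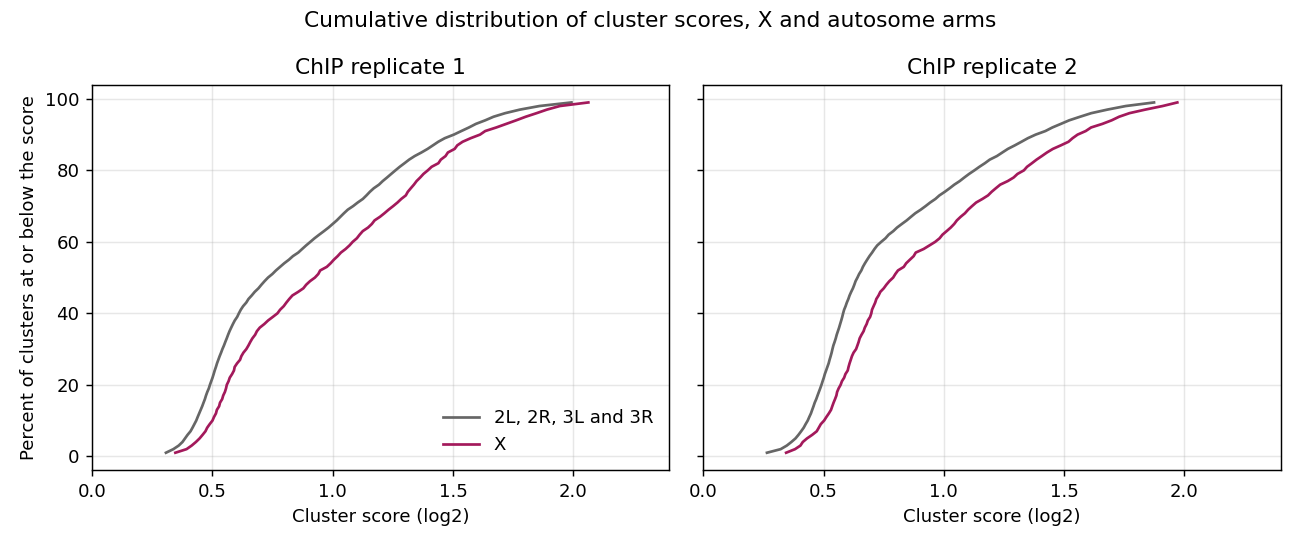
Cumulative distribution of cluster scores (x axis, log2; y axis, percent of clusters at or below the score, drawn from the 1st to the 99th percentile) on X and on the 4 autosome arms in each ChIP replicate. The X curve lies to the right, with medians of 0.93 against 0.73 in replicate 1 and 0.79 against 0.64 in replicate 2.

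Clusters of the Het sequences that were paired between the replicates scored higher than those of the autosome arms, by 0.24 per 100 kb bin (0.11 to 0.39, 25 bins, permutation test, adjusted p = 6e-05), although this too fell, to 0.10 (adjusted p = 0.07, permutation test), in the 50% of clusters with the highest scores. The excess was 0.37 in replicate 1 alone and 0.14 in replicate 2 alone, from 27 and 26 bins. Values of a single list, here and for chromosome 4, are not limited to paired clusters. On chromosome 4 the paired score differed from the autosome arms by -0.05 (-0.14 to 0.04, 13 bins, permutation test, adjusted p = 0.47). The 2 replicates disagreed there: the difference was 0.088 in replicate 1 alone (permutation test, adjusted p = 0.22) and -0.14 in replicate 2 alone (permutation test, adjusted p = 0.018). In the replicate-set list it was 0.13 (-0.0063 to 0.27, permutation test, adjusted p = 0.042), an interval that includes 0, so no direction held for chromosome 4.

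The difference between the replicates itself varied along the chromosomes. On chromosome 4 the median score lay above that of the autosome arms in replicate 1 (0.92 against 0.73) and below it in replicate 2 (0.58 against 0.64). Paired scores were higher in replicate 1 by 0.39 ± 0.21 (SD over 41 pairs) on chromosome 4, where 39 pairs were higher in replicate 1, and by 0.37 ± 0.23 (SD over 36 pairs) on the Het sequences, where 33 were. In the middles of the 5 large arms the difference was 0.04 ± 0.16 (SD over 4072 pairs). It was 0.14 in the 2 Mb of each arm next to the centromere and -0.0015 in the 2 Mb next to the telomere, and all 5 arms were higher at the centromere side, and lower at the telomere side, than in their own middle. Per 100 kb bin, the excess over the arm middles was 0.34 on chromosome 4 (0.26 to 0.41), 0.35 on the Het sequences (0.28 to 0.43) and 0.15 at the centromere sides (0.10 to 0.19), each with an adjusted p of 2e-05 over 8 comparisons by the permutation test, and -0.04 at the telomere sides (-0.06 to -0.01, permutation test, adjusted p = 0.00067). Coverage also differed between the replicates by position. Replicate 2 covered 1.17 to 1.23 times as much as replicate 1 in the telomere-side 2 Mb of the 5 arms, against 1.03 to 1.10 times in the arm middles. At the centromere sides the ratio was 0.893 to 1.09 and lay below that of the arm's own middle in 4 of the 5 arms, the exception being 3R with 1.09 against 1.07. The difference of replicate 2 minus replicate 1 exceeded that of the arm middles by 3.64 percentage points at the telomere sides (2.53 to 4.81, permutation test, adjusted p = 2e-05) and fell short of it on chromosome 4, with -3.54 points (-4.65 to -2.56, permutation test, adjusted p = 0.0018), and on the Het sequences, with -1.21 points (-1.49 to -0.937, permutation test, adjusted p = 0.0039). At the centromere sides this difference from the arm middles was -0.731 points (permutation test, adjusted p = 0.069). These comparisons are in points, and the parts differ widely in covered share. The Het bins themselves changed by -0.2145 points, against 0.995 points in the arm middles. With only 1.22% and 0.969% of the Het sequences covered, their value cannot show a replicate effect particular to them. The lists were called separately, so a score difference between them is not itself a difference in acetylation.

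**Figure D4:**
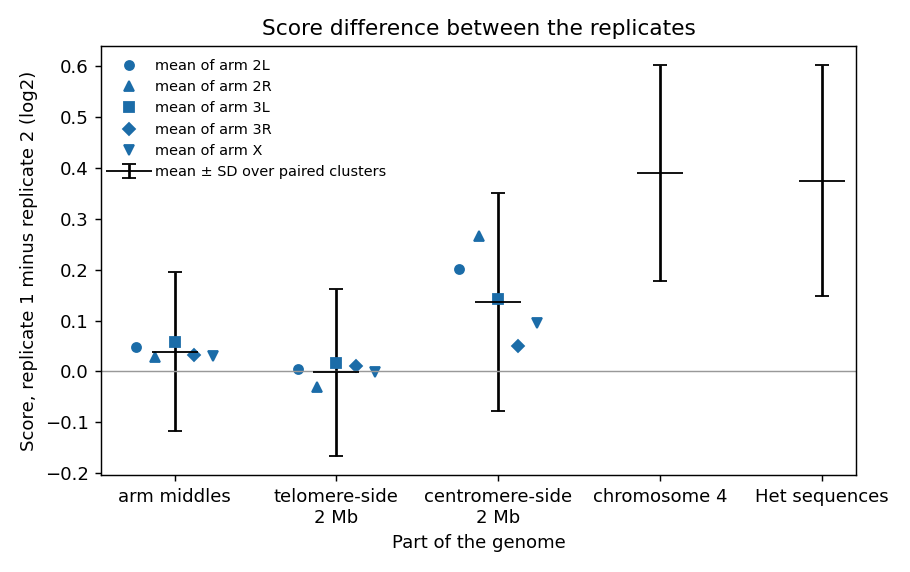
Score of replicate 1 minus score of replicate 2 (y axis, log2) over paired clusters in 5 parts of the genome (x axis). Black bars are means with SD over pairs and blue symbols are means of single arms. Chromosome 4 (0.39) and the Het sequences (0.37) lie above the arm middles (0.04), and all 5 arms are higher at the centromere side than in their middle.

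The list of the replicate set held clusters beyond those of either replicate. It had 10096 clusters over 30.95 Mb, with a median score of 0.43. It contained 99.8% of replicate 1 clusters and 97.8% of replicate 2 clusters, a comparison of lists that come from the same libraries. Of its clusters, 5324 (52.7%) overlapped both replicates' lists, with a median score of 0.80 and a median length of 3458 bp. Another 674 overlapped replicate 1 only and 1353 replicate 2 only, with median scores of 0.34 and 0.36. The remaining 2745 (27.2%) overlapped neither list, with a median score of 0.35 and a median length of 1261 bp, and 1511 of them were shorter than the shortest cluster of 1301 bp in either replicate's list.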

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

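All tests in this part were chosen after the results were seen. The unplaced sequence U, which the comparisons of the chromosomes leave out, held 14 clusters in replicate 1 and 11 in replicate 2. These are counts only, since no expected number of clusters on U is known. No cluster was listed on the larger unplaced sequence Uextra in the 3 lists. In the replicate-set list, 2745 clusters were overlapped by neither replicate's list.

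On X, scores were higher than on the autosome arms while fewer clusters were called. Fewer weak regions called on X cannot be told apart from other explanations: clusters scoring up to 1 were 68.0% as dense on X as on the autosome arms (70.1% in replicate 1, 65.8% in replicate 2), but this follows from the pattern itself. Clusters above 1 were within the range of the 4 arms and denser than on these arms together, at 21.0 against 19.5 per Mb in replicate 1 and 19.4 against 17.3 in replicate 2, and paired clusters above 1 scored higher on X by 0.043 (0.0061 to 0.083, unadjusted permutation p = 0.018), so a lack of clusters up to 1 need not be the whole cause. One offset of all X ratios stays open: averaged over the replicates, the X difference varied by 0.0313 between the 75th, 90th and 95th percentiles. It was not equal over the whole distribution. In replicates 1 and 2 it was 0.061 and 0.048 at the 5th percentile, 0.078 and 0.088 at the 25th, and 0.195 and 0.148 at the median. At the 99th, X scored 2.06 against 1.99 in replicate 1 and 1.97 against 1.87 in replicate 2. An unstated calling threshold could hold low scores together, so the low percentiles cannot decide. A biological difference of X chromatin was not tested, as the design has no group for it. The number of X copies and the read depth on X were not taken into account either.

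Replicate 1 scored above replicate 2 on chromosome 4 and the Het sequences. A score scale difference equal over the genome is argued against by the excess over the arm middles, 0.34 (0.26 to 0.41) on chromosome 4 and 0.35 (0.28 to 0.43) on the Het sequences. A difference that grows with the score is argued against as well, since the excess over the 50 arm-middle pairs of nearest score was 0.33 (0.25 to 0.40) on chromosome 4 and 0.35 (0.27 to 0.42) on the Het sequences. An uneven representation of heterochromatin in a ChIP or an input library, and a biological difference between the larvae collected, stay open, because no read counts of these libraries were used here.

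Of the 12 highest replicate-set scores, 5 belonged to clusters of 1001 to 1013 bp found in neither replicate. Of these, 3 had the same score of 3.08, a ratio of 8.48 on the inferred log2 scale. They lie on 2L at 11316638 to 11317638 and 21653312 to 21654324, and on X at 6324106 to 6325106. All 10 differences between the 5 scores were log2 of ratios of whole numbers with denominators up to 50 (relative tolerance 1e-11), against 0 of 21 among the other 7 clusters. The 5 clusters hold only 3 distinct scores, so this rests on 2 independent differences, and ratios of a few reads may account for it. No biological explanation was tested.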

How the results depend on the processing

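The tests of scores between sequences, the tests between parts of the arms, the arms without their 2 Mb ends and the 1 Mb bins were chosen after seeing the data. Of 73 alternative values, 61 kept their direction and side of the threshold, or for a value with no test moved by less than its spread. Among the 50% of clusters with the highest scores, the coverage difference on X was gone, at 0.112 percentage points (-1.25 to 1.55, permutation test, adjusted p = 0.88). In the same clusters the score excess fell to 0.038 on X and to 0.10 on the Het sequences (each adjusted p = 0.07, permutation test), the chromosome 4 score difference turned to 0.000998, Spearman's rho of paired scores was 0.845 and the centromere-side coverage difference passed the threshold at -1.07 points. These lists hold fewer clusters, and a cut on the score narrows the X score difference by construction. The cut also keeps a larger share of the X clusters than of the autosome clusters, since those on X scored higher. The coverage deficit on X was thus seen only with the lower-scoring clusters included. In 1 Mb bins the X coverage difference was of similar size, -2.16 points (-4.32 to -0.0683), but did not pass (permutation p = 0.099), with 22 X bins. The chromosome 4 score difference ranged from -0.14 to 0.088 when 1 replicate was left out, with scores then not limited to paired clusters. It passed the threshold in opposite directions without replicate 1 (-0.14, adjusted p = 0.018, permutation test) and in the replicate-set list (0.13, -0.0063 to 0.27, adjusted p = 0.042, permutation test), where the interval includes 0; the cause was not tested. Leaving out a replicate moved the X coverage difference between -3.53 and -2.78 points, that of chromosome 4 between -11.1 and -7.22 and that of the Het sequences between -18.3 and -16.7. The score excess ranged from 0.13 to 0.14 on X and from 0.14 to 0.37 on the Het sequences. The coverage values of a single list count all sequence it covers, while the main values count only sequence covered in both replicates. With 50 kb bins the centromere-side coverage difference was -0.759 points and passed, and with a minimum overlap of 50% of a cluster's length rho was 0.910. Overlaps between lists stayed above their shifts (permutation p = 0.001) in each alternative run. Those with the replicate-set list compare lists from the same libraries, so they are not an independent check, and the 61 values include them. No paired analysis was possible because the input libraries that share replicate numbers with the ChIP libraries enter with no values. The alternatives for promoters and gene lists were not run, for want of an annotation of release 5. Unknown depth limits what can be said of weak clusters, where the replicates overlapped least.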

Other observations

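H3K9ac coverage thinned towards the centromere on 4 of the 5 large arms. In the 2 Mb next to the centromere, the share covered in both replicates was 3.82% on 3L, 5.37% on X, 6.52% on 2R and 6.91% on 2L, against 12.98% to 18.6% in the arm middles. On 3R it was 18.9%, above the 15.8% of its middle. The telomere-side 2 Mb were covered more than the middle on 4 arms, from 17.8% on X to 24.8% on 2R, and less on 3R, with 13.7% against 15.8%. These values were computed after the data were seen and were not tested.

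Within the Het sequences, XHet was covered most, at 4.51% in replicate 1 and 4.34% in replicate 2, and 3RHet least in replicate 1, at 0.710%. All 3 clusters of 2LHet in replicate 1 scored above 1, and the median score there was 1.69 in replicate 1 and 1.18 in replicate 2.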
